A study of Homo sapiens with 10 samples.

How the data were processed

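Gene expression was measured in 10 human breast cancer libraries, 1 for each of 6 established cell lines and 4 fusions of a basal-like with a luminal line. Per the labels' protocols, polyA RNA was made into first-strand cDNA, tailed and read as single molecules on a Helicos HeliScope instrument (digital gene expression). The submitters' processing notes give the genome build hg18. The aligner, the counting rule, the strand and the gene annotation are not given in the sources used here.

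The deposited table holds RPM (read numbers scaled to the reads assigned to genes) as the authors computed them, with 2 decimals. The 10 columns summed to between 999895 and 1000003 RPM. The table lists 28807 genes, of which 2 with a missing BT-474 value were left out, so 28805 were used. Only 37.2% to 50.6% of the low values were multiples of the commonest low value, so whole read counts could not be had back; the cause was not tested. Count models were therefore not used. The value of 1 read, taken from the commonest low value of each column, gave estimated depths of 1.05 M reads (T-47D) to 4.35 M reads (BT-474). At these depths counting error alone gives a coefficient of variation of 21.4% to 43.7% at 5 RPM and 10.7% to 21.8% at 20 RPM. A gene listed at 0 is compatible with a level of up to 0.69 RPM in BT-474 and up to 2.86 RPM in T-47D, taken as 3 reads. These limits cover counting error only. How reads that match several members of a gene family were counted is not given, so levels of single keratins, HLA genes and metallothioneins are uncertain in that respect, which was not tested.

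Symbols are printed as the table gives them. A current RefSeq gene table matched 14828 of the genes by symbol and 3976 by an older symbol, and 10001 had no unique match. Older symbols used below are UTX for KDM6A, TACSTD1 for EPCAM, RBM35A and RBM35B for ESRP1 and ESRP2, IL8 for CXCL8 and C3ORF57 for SPTSSB. MTD maps to the same current gene as MT1E. The RefSeq table served for symbols and for the order of neighbouring genes; no coordinates are given, since its build differs from hg18.

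The labels' cell type gave the groups: basal-like (n = 3), luminal (n = 3) and heterofusion (n = 4). Replicate numbers follow the order of the samples: basal-like SUM159PT, MDA-MB-231 and Hs578T; luminal MCF7, T-47D and BT-474; fusions MDA-MB-231_MCF7, SUM159PT_T-47D, SUM159PT_BT-474 and SUM159PT_MCF7. Cell lines of 1 class stood in for replicates, and nothing in the labels tells of separate cultures of 1 line. RPM was analysed as log2(RPM + 1) for the 12738 genes at 5 RPM or more in at least 3 libraries. All 10 libraries entered 1 linear model of the 3 groups in limma 3.58.1 (lmFit, then eBayes with a trend, R 4.3.3), and p-values were adjusted by Benjamini-Hochberg within each comparison, two-sided, with a threshold of 0.05. The 3 comparisons were basal-like against luminal, fusion against luminal, and fusion against basal-like. A fitted fold change against a group near 0 RPM depends on the pseudocount of 1, and none is given against a group listed at 0 throughout.

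The numbers do not pair the libraries, but the names of the 3 SUM159PT fusions do, since each names another luminal parent. Across genes, the deviation of each of these fusions from their mean correlated with that of its own luminal parent at r of 0.197 (T-47D), 0.229 (BT-474) and 0.244 (MCF7), and with those of the other luminal lines at −0.142 to −0.0916. A fit with the luminal parent as a block was therefore run beside the unpaired one.

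The 25 gene lists named 385 entries, of which 383 were in the table. They covered luminal transcription factors, luminal differentiation, epithelial junction and splicing, basal and myoepithelial, mesenchymal, EMT transcription factors, 4 study regulators (EN1, TBX18, TCF4 and UTX, which the study examined and may have picked with the help of these libraries), extracellular matrix, oestrogen receptor targets, the ERBB2 amplicon, proliferation, interferon response, MHC class I, NF-kB and cytokines, chromatin regulators, hypoxia and glycolysis, cholesterol synthesis, unfolded protein response, immediate early and stress, housekeeping, ribosomal proteins, and markers of leukocytes, endothelium, fibroblasts and adipocytes. Some genes sit in more than 1 list, as ZEB1 in the mesenchymal and EMT lists. EN1, TBX18 and TCF4 are study regulators and also EMT transcription factors, so the EMT list is to that extent no independent evidence. The 22 lists with at least 3 tested genes were put to camera (limma) with a preset correlation of 0.01, and again with an estimated correlation; members past the threshold were counted over all genes and adjusted over the list alone.

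Each fusion was also set against its own 2 parents. Genes qualified when the parents differed at least 4-fold on RPM + 1 and the higher parent had at least 20 RPM, and the fusion was compared with the mean of the 2 parental RPM values, the level expected if both genomes kept their activity. The difference between the medians of basal-high and luminal-high genes was tested across the 4 fusions by an exact sign-flip permutation, whose smallest two-sided p is 0.125. The spread within a class was the mean over pairs of lines of 1 − Pearson r and of the median absolute log2 difference, tested by an exact permutation of the 6 parental lines (20 assignments, smallest two-sided p 0.1). Apart from the real grouping and its reverse, the assignments mix the classes, so their values also carry the distance between classes. The overlap of the 2 comparisons that share the luminal libraries was set against simulated groups with no change.

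The groups, comparisons, gene lists, tests, alternatives and the rule for the genes named were chosen before the data were examined. The rule took the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, up to 4 members past the threshold per list, 13 genes whatever their result (EN1, TBX18, TCF4, KDM6A, ESR1, GATA3, FOXA1, CDH1, VIM, ZEB1, KRT5, KRT18 and ERBB2), the 4 lowest and 4 highest genes on each side in the comparison with the parents, and the 5 genes of largest SD in each class. Alternatives changed the pseudocount, the filter, the scaling (TMM factors or quantile normalization), the variance prior, the libraries in the fit, and left out each library in turn. Count tests on whole reads had been foreseen and were not run, because whole reads could not be had back.

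The procedure was tested on simulated data of the same size with 200 changed genes per run in 5 runs. It recovered 2.4% to 5.2% of 2-fold changes, 42.8% to 49.2% of 4-fold changes, 74.0% to 83.2% of 8-fold changes and 87.2% to 89.6% of 16-fold changes over the 3 comparisons, and 4.44% to 5.78% of the genes called were false. The changed genes were drawn from those averaging 20 RPM or more over the libraries, and all libraries were drawn as independent. Recovery of less abundant genes, or with 3 fusions that share SUM159PT, was not tested and may be poorer. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.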

Results

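Digital gene expression was profiled in basal-like lines, luminal lines and fused cells made from 1 line of each class, which addresses how much of either program a fused cell keeps and how alike basal-like lines are. The basal-like lines were SUM159PT, MDA-MB-231 and Hs578T (n = 3), the luminal lines were MCF7, T-47D and BT-474 (n = 3), and the 4 fusions were MDA-MB-231_MCF7, SUM159PT_T-47D, SUM159PT_BT-474 and SUM159PT_MCF7. Each line or fusion had 1 library. SUM159PT was a parent of 3 fusions, which are therefore not independent, and Hs578T was a parent of none. Estimated depths were 1.05 M reads in T-47D, 1.29 in SUM159PT, 1.63 in MCF7, 1.71 in SUM159PT_T-47D, 1.75 in MDA-MB-231, 2.26 in SUM159PT_MCF7, 2.28 in MDA-MB-231_MCF7, 2.68 in Hs578T, 2.79 in SUM159PT_BT-474 and 4.35 in BT-474. The libraries held 10753 to 11590 genes at 5 RPM or more, and the 10 most abundant genes took 6.17% to 9.63% of the reads. No sequencing batch or date is given in the labels.

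**Figure D1:**
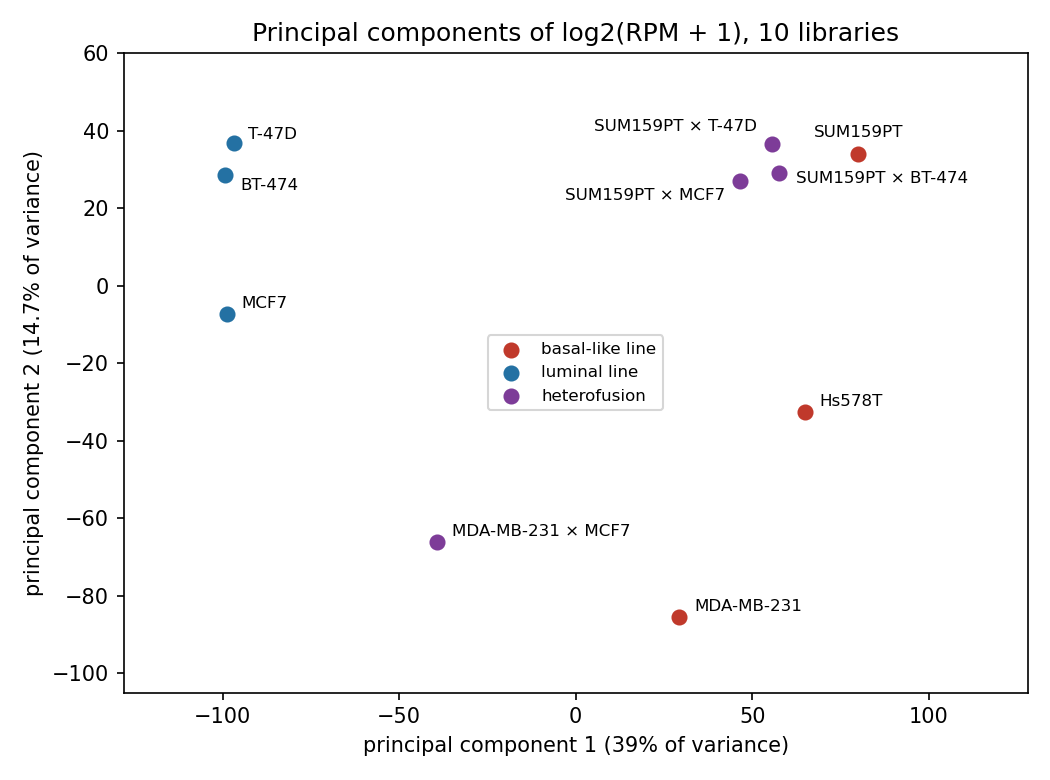
First and second principal component (unitless scores, 39% and 14.7% of the variance) of log2(RPM + 1) over 12738 genes, 1 point per library, coloured by group. The luminal lines sit between −99.2 and −96.88 on the first component, the SUM159PT fusions between 46.57 and 57.58, and MDA-MB-231_MCF7 at −39.24.

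Basal-like and luminal lines were compared first, to define the genes that separate the classes. VIM averaged 4978 RPM ± 2078 (SD, n = 3) in the basal-like lines and 13.9 ± 23.1 (n = 3) in the luminal lines, a log2 fold change of 10 (SE 1.83, limma adjusted p = 0.00931). GSTP1 (559 RPM ± 15.3), MSN (308 ± 21.0) and SERPINE1 (366 ± 228) were present in all 3 basal-like lines and listed at 0 in all 3 luminal lines, with adjusted p of 2.85e-08, 2.44e-05 and 0.00138. AKR1B1 (700.4 ± 693 against 0.307 ± 0.531 RPM), AXL (551 ± 378 against 0.943 ± 0.305), IGFBP7 (932 ± 909.7 against 1.003 ± 0.787) and IL8 (462 ± 366 against 1.51 ± 2.42) were also higher, with adjusted p of 2.44e-05, 0.000455, 0.00200 and 0.00125. MT1E (483 ± 372 RPM) and MTD (335 ± 226), which map to the same current gene, completed the 10 largest rises, with adjusted p of 0.000414 and 0.000346. In the other direction, FOXA1 averaged 0.51 ± 0.442 RPM in the basal-like and 311 ± 44.6 in the luminal lines (log2 fold change −7.73, SE 1.33, adjusted p = 0.00650), and GATA3 averaged 14.3 ± 13.3 against 1211 ± 858 (−6.35, SE 1.23, adjusted p = 0.0116). ESR1, the oestrogen receptor gene, averaged 0.51 ± 0.442 against 77.4 ± 36.7 RPM (−5.62, SE 0.69, adjusted p = 0.00158). IGFBP5 (3.56 ± 4.99 against 969 ± 632 RPM), AGR2 (0.64 ± 0.583 against 727 ± 761) and the unnamed transcript AF401033 (0.197 ± 0.341 against 472 ± 432) were lower, with adjusted p of 0.00315, 0.00767 and 0.00315. TFF3 (1068 ± 1662 RPM in luminal lines), FXYD3 (527 ± 391) and C3ORF57 (588 ± 903) were listed at 0 in all 3 basal-like lines, with adjusted p of 0.00326, 0.0138 and 0.0158. Without MCF7 the call of C3ORF57 was lost (adjusted p = 0.0519, in a range of 0.00229 to 0.0519 over 19 alternatives).

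Of 12738 genes, 980 passed the threshold in limma, 603 higher and 377 lower in basal-like lines, and 3101 had an unadjusted p under 0.05. The 2 groups did not overlap for 975 of these 980 genes and for 25.31% of all genes tested, where chance gives 10%. The count changed with the libraries in the fit. It was 629 (without Hs578T) to 724 (without MDA-MB-231) with 1 parental line left out. Without 1 SUM159PT fusion it was 753 to 815, and without MDA-MB-231_MCF7 1202. In a fit of the 6 parental lines alone it was 615. The count fell without any 1 parental line, so the fall is not particular to Hs578T. CDH1, the E-cadherin gene, averaged 0.453 ± 0.405 RPM in the basal-like and 265 ± 39.3 in the luminal lines (log2 fold change −7.54, SE 1.76, adjusted p = 0.0257). GRHL2 (listed at 0 against 120 ± 64.0 RPM, adjusted p = 0.0263) and MAL2 (0.38 ± 0.658 against 359 ± 131, adjusted p = 0.0330) passed as well. The calls of CDH1, GRHL2 and MAL2 were lost without any 1 of the 6 parental lines. The highest adjusted p was 0.0712 for CDH1 without Hs578T, 0.0790 for GRHL2 without T-47D and 0.0891 for MAL2 without BT-474, and the lowest over 19 alternatives were 3.01e-05, 0.000153 and 4.26e-05. KRT18 (235 ± 113 against 2460 ± 1492 RPM, log2 fold change −3.36, SE 0.88, adjusted p = 0.0415), KRT19 (69.6 ± 121 against 1516 ± 259.7 RPM, adjusted p = 0.0488) and ZEB1 (22.4 ± 12.8 against 0.27 ± 0.468 RPM, log2 fold change 4.07, SE 1.06, adjusted p = 0.0405) stood close to the threshold as well. Over 19 alternatives their adjusted p ranged from 0.00232 to 0.121 for KRT18, from 0.0146 to 0.142 for KRT19 and from 0.00216 to 0.118 for ZEB1. KRT18 and ZEB1 were lost without any 1 of the 6 parental lines, and KRT19 without any of them but MDA-MB-231. All 3 were also lost without SUM159PT_T-47D or SUM159PT_BT-474, and ZEB1 without SUM159PT_MCF7. With no filter on low values the calls of CDH1, GRHL2, MAL2, KRT18, KRT19 and ZEB1 were all lost. The same calls were all kept without MDA-MB-231_MCF7 and in a fit of the 6 parental lines alone. KRT18 and KRT19 were also lost with eBayes without trend or robust, MAL2 with eBayes robust, KRT19 with a pseudocount of 0.5 or quantile normalization, and ZEB1 with a filter of 20 RPM.

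Of the genes followed whatever their result, EN1 (7.08 ± 6.46 RPM in basal-like and 0.393 ± 0.681 in luminal lines), TCF4 (23.9 ± 22.8 against 3.34 ± 2.10) and TBX18 (7.64 ± 12.9 against listed at 0) did not pass, with limma adjusted p of 0.316, 0.460 and 0.571. Neither did UTX (14.1 ± 9.04 against 17.7 ± 3.12, adjusted p = 0.604) or ERBB2 (23.0 ± 2.17 against 497 ± 782, adjusted p = 0.177). TBX18 was at 22.55 RPM in SUM159PT, 0 in MDA-MB-231 and 0.37 in Hs578T. EN1 was at 8.56, 0 and 12.67 RPM and TCF4 at 24.89, 0.57 and 46.22 RPM in the same lines. ERBB2 stood at 1400.9 RPM in BT-474 and at 36.28 and 55.18 RPM in the other luminal lines. KRT5 had at most 0.23 RPM in the 6 parental lines and was not tested.

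**Figure D2:**
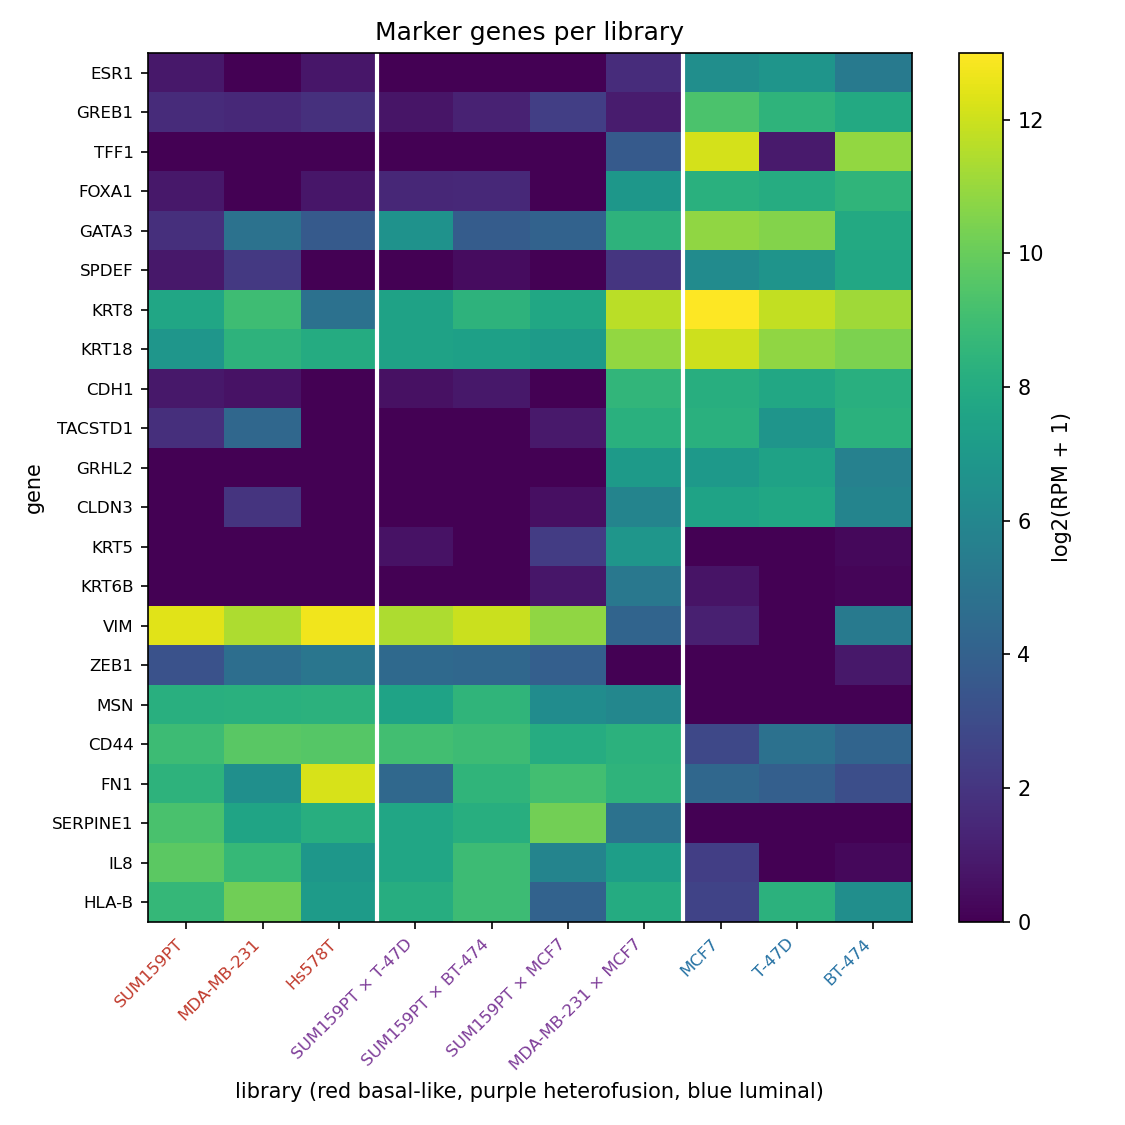
Levels of marker genes in each of the 10 libraries, as log2(RPM + 1) on a colour scale, with libraries ordered by group. CDH1 is at 381.79 RPM in MDA-MB-231_MCF7 and at 0.77 RPM or less in the SUM159PT fusions, and VIM at 17.53 RPM against 1809 to 3938 RPM.

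The gene lists gave the same contrast between classes by group of function. Of 22 tested mesenchymal genes, 16 were higher and 0 lower in basal-like lines over all genes (20 and 0 adjusted over the list alone), with a median log2 fold change of 5.49 and a camera adjusted p of 1.01e-17. Luminal transcription factors had 0 higher and 7 lower of 15 (0 and 11 adjusted over the list alone, median −3.22, camera adjusted p = 6.39e-10). Luminal differentiation genes had 0 and 8 of 17 (0 and 11, median −4.17, 4.04e-08) and oestrogen receptor targets 0 and 6 of 13 (0 and 7, median −1.85, 1.85e-05). These 4 lists also passed with an estimated correlation, at adjusted p of 0.0279, 0.0302, 0.0289 and 0.0279. Among the oestrogen receptor targets, GREB1 averaged 2.10 ± 0.312 RPM against 404 ± 204 (log2 fold change −6.91, SE 0.53, adjusted p = 8.94e-05) and XBP1 134 ± 41.7 against 1093 ± 69.8 (−3.06, SE 0.36, adjusted p = 0.00127).

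Of 24 epithelial junction and splicing genes, 0 were higher and 13 lower (0 and 23 adjusted over the list alone), with a median of −5.10, camera adjusted p = 1.32e-15, but adjusted p = 0.190 with an estimated correlation. Extracellular matrix genes had 6 higher of 17 (12 adjusted over the list alone, camera adjusted p = 1.51e-07) and NF-kB and cytokine genes 6 of 16 (9 adjusted over the list alone, 1.51e-07), both at adjusted p = 0.190 with an estimated correlation. EMT transcription factors had 5 higher of 12 (5 adjusted over the list alone) and MHC class I genes 4 of 10 (6 adjusted over the list alone), both with camera adjusted p = 3.88e-05 and adjusted p = 0.203 with an estimated correlation. COL8A1 (203 ± 130 RPM against 0.153 ± 0.266, adjusted p = 0.0111), IL6 (29.8 ± 10.6 against 0.41 ± 0.710, 0.0135) and FOSL1 (190 ± 177 against 1.1 ± 1.71, 0.00158) were among the members past the threshold, as were SNAI2 (104 ± 113 against 3.01 ± 5.16 RPM, adjusted p = 0.0104) and B2M (4607 ± 827 against 964 ± 470.4, log2 fold change 2.39, SE 0.47, 0.0121). Hypoxia and glycolysis genes had 6 higher of 14 (7 adjusted over the list alone, camera adjusted p = 0.000197, adjusted p = 0.0532 with an estimated correlation), with NDRG1 at 121 ± 5.43 against 17.3 ± 19.5 RPM (log2 fold change 3.28, SE 0.65, adjusted p = 0.0125).

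Lower-ranking lists depended on single lines. The ERBB2 amplicon (0 called of 7 over all genes and 0 adjusted over the list alone, camera adjusted p = 0.0161, lower, adjusted p = 0.527 with an estimated correlation) had an adjusted p of 0.364 without BT-474. Proliferation genes (2 higher of 27, 4 adjusted over the list alone, 0.0416, adjusted p = 0.583 with an estimated correlation) had 0.0504 without MDA-MB-231_MCF7, 0.167 without MCF7 and 0.345 without MDA-MB-231. Fibroblast markers (1 higher of 4, 3 adjusted over the list alone, 0.0156, adjusted p = 0.349 with an estimated correlation) had 0.0901 without Hs578T, the line that held all 9 of these markers above 5 RPM. Basal and myoepithelial genes (4 higher and 0 lower of 15, 5 and 2 adjusted over the list alone) had a camera adjusted p of 0.0745, and 0.00788 without MCF7. The interferon list (1 higher of 15, 0.399) had 0.0154 without MCF7, ribosomal proteins (1 higher of 20, 0.121) 0.00795 without SUM159PT, cholesterol synthesis (0 of 14, 0.522) 0.0285 without Hs578T, and immediate early and stress genes (2 higher of 12, 0.127) 0.0117 without BT-474. The study regulators EN1, TBX18, TCF4 and UTX (0 of 4, 0.522), which the study chose and which are no independent evidence, did not pass. Neither did chromatin regulators (0 of 14, 0.522), the unfolded protein response (1 higher and 1 lower of 14, 0.598) or housekeeping genes (0 of 12, 0.598). Of the leukocyte markers 2 were tested, of which CD68 was higher (75.1 ± 48.0 against 2.08 ± 1.20 RPM, log2 fold change 4.49, SE 0.53, limma adjusted p = 0.00127). Of the endothelial markers 1 was tested and not called, and of the adipocyte markers 0 were tested.

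Fusions were compared with luminal lines to ask how far fused cells depart from the luminal program. GSTP1 averaged 266 RPM ± 64.1 (n = 4) in the fusions and MSN 172 ± 137, and both were listed at 0 in the 3 luminal lines, with limma adjusted p of 5.68e-08 and 4.95e-05. AKR1B1 averaged 549 ± 151 RPM in the fusions against 0.307 ± 0.531 (log2 fold change 8.75, SE 0.54, adjusted p = 2.12e-05) and SRGN 412 ± 196 against 4.57 ± 5.98 (6.57, SE 0.71, adjusted p = 0.000861). IL8 averaged 223 ± 179 against 1.51 ± 2.42 (6.53, SE 0.83, adjusted p = 0.00230) and TGFBI 395 ± 249 against 7.3 ± 9.81 (6.17, SE 1.06, adjusted p = 0.0111). SERPINE1 (431 ± 524 RPM, listed at 0 in luminal lines) had an adjusted p of 0.00172. GREB1 averaged 1.86 ± 1.72 RPM against 404 ± 204 (−7.19, SE 0.49, adjusted p = 3.61e-05) and ESR1 0.548 ± 1.095 against 77.4 ± 36.7 (−5.74, SE 0.65, adjusted p = 0.00109). SPDEF averaged 0.858 ± 1.48 against 134 ± 76.4 (−6.32, SE 0.70, adjusted p = 0.00104) and XBP1 115 ± 44.3 against 1093 ± 69.8 (−3.32, SE 0.34, adjusted p = 0.000796). IGFBP5 (5.13 ± 10.02 against 969 ± 632 RPM, adjusted p = 0.00230) and TFF3 (1.88 ± 1.97 against 1068 ± 1662, adjusted p = 0.00726) were lower in the fusions, and ALDH3B2 (143 ± 194 RPM in luminal lines, adjusted p = 0.00417) was listed at 0 in all 4. MT1E (199 ± 148 RPM, adjusted p = 0.000833), MTD (198 ± 157, 0.000701) and a transcript entry of HLA-A (416 ± 149 against 19.2 ± 31.9, 0.0123) completed the 10 largest rises. The unnamed transcripts AF401033, AF401035, AK001889 and BC071816, at 331 to 472 RPM in luminal lines for the first 3 and 231 RPM for the last, averaged 0.765 RPM or less in fusions, with adjusted p of 0.00292, 0.00484, 0.00283 and 0.00566. AGR2 (12.8 ± 23.1 against 727 ± 761 RPM, adjusted p = 0.0231) completed the falls. Its call was lost with no filter on low values and without any 1 SUM159PT fusion, T-47D or BT-474, at up to 0.0937 in a range from 0.00164, and that of the HLA-A entry without BT-474, at 0.0605 in a range from 0.000352.

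In limma 357 genes passed the threshold, 258 higher and 99 lower in fusions, and 2339 had an unadjusted p under 0.05. The groups did not overlap for 355 of the 357 and for 16.99% of all genes tested, where chance gives 5.71%. With the 3 SUM159PT fusions alone the count was 835 (525 higher, 310 lower), which held 354 of the 357. With the luminal parent as a block, these 3 fusions and their 3 luminal parents gave 1288 genes (791 higher, 497 lower), and the same 6 libraries without the block gave 1201 (757 and 444). Fusions that share SUM159PT are not independent, so these larger counts describe fusions of that line only. The count was 155 without SUM159PT_T-47D, 159 without SUM159PT_BT-474, 163 without SUM159PT_MCF7, 217 without T-47D and 196 without BT-474. The share of higher genes among those called ranged from 57.4% to 81.7% over 22 alternatives. It was 57.4% with no filter on low values and 81.7% with a filter of 20 RPM, 57.5% with a pseudocount of 5 and 77.1% with one of 0.5, and 61.8% after quantile normalization.

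Genes of the epithelial and mesenchymal states lay on both sides of the threshold, and MDA-MB-231_MCF7 differed from the other fusions. CDH1 was at 381.79 RPM in MDA-MB-231_MCF7 and at 0 to 0.77 RPM in the 3 SUM159PT fusions, and the 4 fusions against luminal lines gave a limma adjusted p of 0.101. For the 4 fusions together GATA3 (0.0879), KRT18 (0.0896), ZEB1 (0.151) and TBX18 (0.151) did not pass, nor did EN1 (0.402), TCF4 (0.679), UTX (0.792) and ERBB2 (0.329). With the 3 SUM159PT fusions alone more calls were made. There 6 of 12 EMT transcription factors were higher, against 3 with all 4 fusions, and 1 of 4 study regulators, against 0. EN1, TBX18 and TCF4 are in both lists, so these counts are not separate results. VIM, at 17.53 RPM in MDA-MB-231_MCF7 and 1809 to 3938 RPM in the others, passed at an adjusted p of 0.0446 (log2 fold change 7.42, SE 1.72), which ranged from 0.000980 to 0.145 over 22 alternatives. The call of VIM was lost without any 1 SUM159PT fusion, any 1 basal-like line, MCF7 or T-47D. It was also lost with a pseudocount of 5, with no filter on low values, after quantile normalization, in a fit of the 2 groups alone, and with eBayes without trend or robust. FOXA1 (29.7 ± 57.1 against 311 ± 44.6 RPM, −5.82, SE 1.24, adjusted p = 0.0316) ranged from 5.90e-05 to 0.108 and was lost without any 1 SUM159PT fusion or any 1 luminal line, with no filter on low values and in a fit of the 2 groups alone. KRT5 was at 110.83 RPM in MDA-MB-231_MCF7 and at 3.98 RPM or less in the other 9 libraries, and was not tested.

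Mesenchymal genes had 8 higher and 0 lower of 22 in fusions against luminal lines (20 and 0 adjusted over the list alone), with a median log2 fold change of 4.35 and a camera adjusted p of 8.03e-15. Luminal transcription factors had 0 and 4 of 15 (0 and 7 adjusted over the list alone, 4.16e-11), luminal differentiation genes 0 and 2 of 17 (0 and 10, 1.19e-07) and oestrogen receptor targets 0 and 4 of 13 (0 and 6, 3.91e-07). These 4 lists passed with an estimated correlation too, at adjusted p of 0.0266, 0.0266, 0.0266 and 0.0174. Epithelial junction and splicing genes had 0 and 2 of 24 (0 and 15 adjusted over the list alone, 2.01e-14, adjusted p = 0.194 with an estimated correlation). In the 3 SUM159PT fusions alone 19 of these 24 genes were lower, and the list passed with an estimated correlation, at adjusted p = 0.0127. These 3 share a parent and are not independent, so that result covers fusions of SUM159PT only. NF-kB and cytokine genes (5 higher of 16, 11 adjusted over the list alone, 1.64e-09) had adjusted p = 0.173 with an estimated correlation. EMT transcription factors (3 higher of 12, 6 adjusted over the list alone, 1.71e-05), extracellular matrix (1 of 17, 8 adjusted over the list alone, 4.56e-06) and MHC class I genes (2 of 10, 6 adjusted over the list alone, 6.85e-05) each had adjusted p = 0.194 with an estimated correlation. RUNX2 (54.2 ± 15.6 against 6.22 ± 3.18 RPM, log2 fold change 3.01, SE 0.41, adjusted p = 0.00315) was the EMT factor with the lowest p of the 3, and FOSL1 (48.2 ± 18.7 against 1.1 ± 1.71, adjusted p = 0.00566) passed as well.

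The other lists past the camera threshold in this comparison were lost without single libraries. Proliferation (0 of 27 called over all genes and 0 adjusted over the list alone, higher, 0.00716, adjusted p = 0.468 with an estimated correlation) had 0.0751 without MCF7. Hypoxia and glycolysis (2 higher of 14 over all genes and 2 adjusted over the list alone, 0.0194, adjusted p = 0.194 with an estimated correlation) had 0.0657 without MDA-MB-231_MCF7 and 0.122 without T-47D. Basal and myoepithelial genes (2 higher of 15, 6 higher and 1 lower adjusted over the list alone, 0.0250, adjusted p = 0.194 with an estimated correlation) had 0.226 without MDA-MB-231_MCF7 and 0.133 without BT-474. The ERBB2 amplicon (0 of 7 over all genes and 0 adjusted over the list alone, lower, 0.0250, adjusted p = 0.541 with an estimated correlation) had 0.0732 without MDA-MB-231_MCF7, 0.0641 without SUM159PT_MCF7 and 0.940 without BT-474. Fibroblast markers (0 of 4 over all genes and 0 adjusted over the list alone, higher, 0.0250, adjusted p = 0.423 with an estimated correlation) had 0.0740 without MCF7, 0.0549 without T-47D and 0.0584 without SUM159PT_MCF7. In the 3 SUM159PT fusions and their 3 luminal parents, hypoxia genes had 0.0832 without and 0.0883 with the luminal parent as a block, basal and myoepithelial genes 0.313 and 0.217, the study regulators 0.0185 and 0.0392, and the ERBB2 amplicon 0.117 and 0.0151. Cholesterol synthesis (0.124) had 0.0447 without SUM159PT_T-47D and immediate early and stress genes (0.203) 0.0108 without BT-474. The median of the interferon list was −0.24 while its mean (0.37) and test direction were positive, and for ribosomal proteins the median (−0.01) and the test were negative and the mean 0.04. Neither list passed, at camera adjusted p of 0.964 and 0.871, nor did the study regulators (0.324), chromatin regulators (0.737), the unfolded protein response (0.871) or housekeeping genes (0.871).

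**Figure D3:**
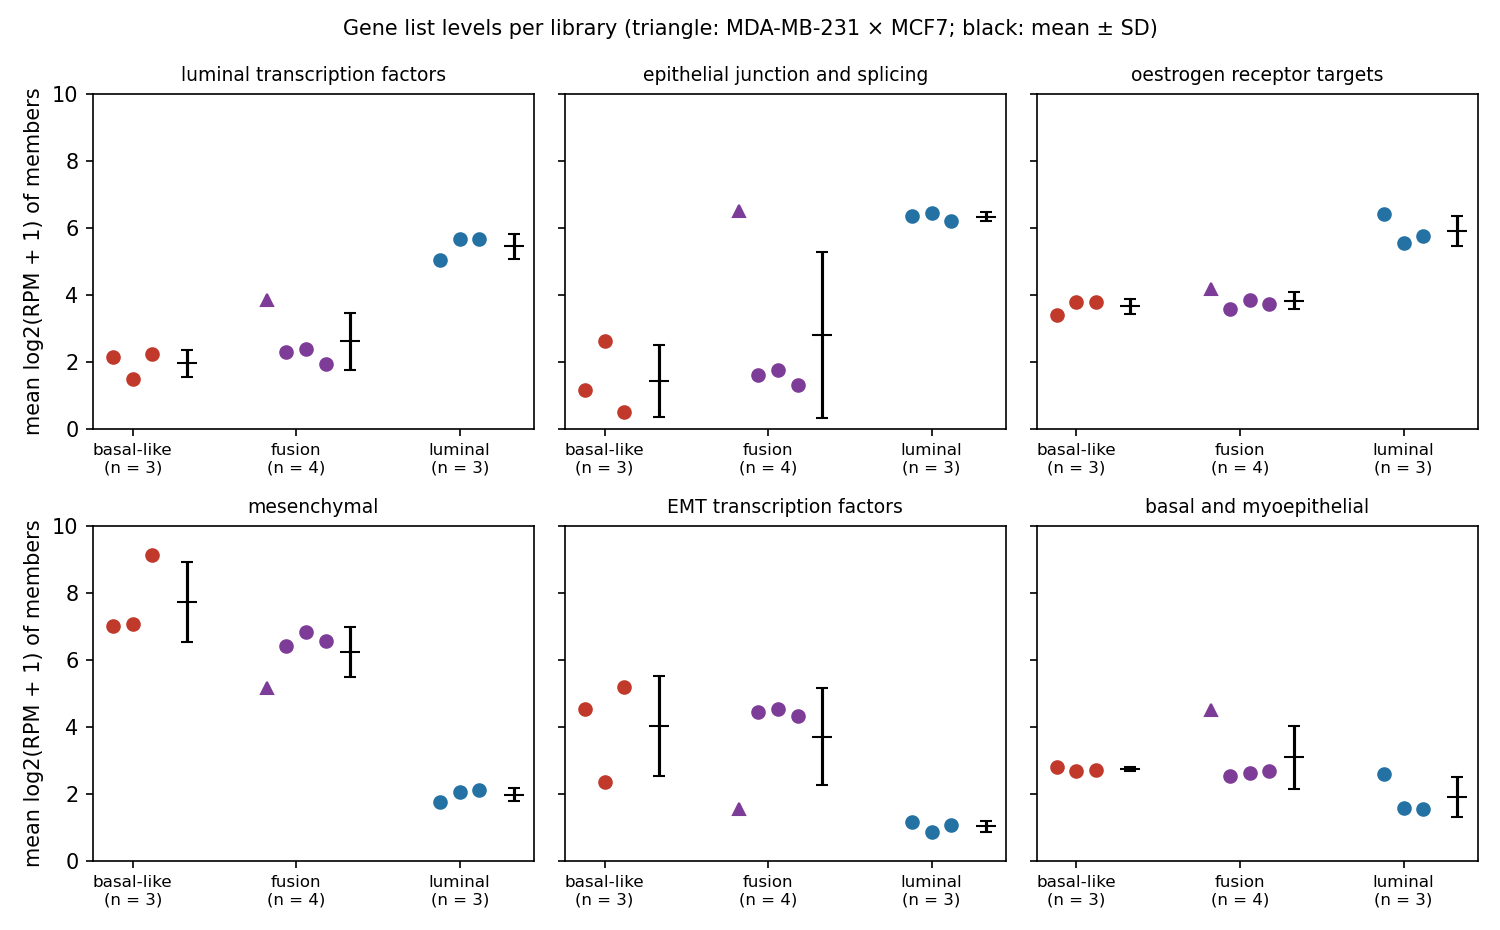
Mean log2(RPM + 1) of 6 gene lists, 1 point per library, with black marks for the group mean ± SD (n = 3, 4 and 3) and a triangle for MDA-MB-231_MCF7. The epithelial junction and splicing list is at 6.48 in MDA-MB-231_MCF7, between 1.3 and 1.76 in the SUM159PT fusions and between 6.18 and 6.44 in the luminal lines.

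Fusions were then compared with basal-like lines, to ask whether fused cells differ from the basal-like class. The fixed genes did not separate these groups in limma. VIM averaged 2115 ± 1649 RPM (n = 4) in fusions and 4978 ± 2078 (n = 3) in basal-like lines (log2 fold change −2.59, SE 1.72, adjusted p = 0.932). GATA3 averaged 115 ± 151 against 14.3 ± 13.3 (2.29, SE 1.15, adjusted p = 0.931), and TBX18 averaged 44.6 ± 38.1 against 7.64 ± 12.9 (2.67, SE 1.49, adjusted p = 0.931). CDH1, EN1, ERBB2, ESR1, FOXA1, KRT18, TCF4, UTX and ZEB1 had adjusted p of 0.932 to 0.992. Of 12738 genes 0 passed the threshold in limma, 669 had an unadjusted p under 0.05, and the smallest adjusted p was 0.489. The groups did not overlap for 7.28% of the genes, where chance gives 5.71%. Without SUM159PT, the parent of 3 fusions, 4 genes passed. These were IGFBP7 (log2 fold change −7.74, SE 0.58, adjusted p = 0.00110), ALCAM (−4.20, SE 0.40, adjusted p = 0.00563), NEBL (4.25, SE 0.49, adjusted p = 0.0206) and TRAM2 (−2.81, SE 0.34, adjusted p = 0.0232). ALCAM, NEBL and TRAM2 were chosen after their values were seen. In SUM159PT the 4 genes were at 55.22, 45.89, 12.69 and 23.9 RPM. They were at 869.36, 216.34, 0.57 and 277.03 RPM in MDA-MB-231 and at 1871.45, 344.77, 0.39 and 230.77 RPM in Hs578T. TRAM2 was lower in SUM159PT than in its fusions (28.06 to 40.96 RPM). This fit sets mostly SUM159PT fusions against other lines, so an effect of fusion cannot be told from a difference between lines. On simulated data of this size, with independent libraries, 49.2% of 4-fold and 74.4% of 8-fold changes were recovered among genes averaging 20 RPM or more.

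Some lists shifted although no member passed over all genes. Mesenchymal genes were lower in fusions (median log2 fold change −1.41, 21 of 22 genes negative, 0 higher and 2 lower adjusted over the list alone, camera adjusted p = 1.09e-08), with adjusted p = 0.168 with an estimated correlation, and this call was kept without each of the 10 libraries. Hypoxia and glycolysis genes were lower (−0.66, 0 and 3 adjusted over the list alone, 0.00127), with adjusted p = 0.168 with an estimated correlation and 0.0629 without SUM159PT. Epithelial junction and splicing genes were higher (1.52, 0 and 0 adjusted over the list alone, 6.10e-05), with adjusted p = 0.861 with an estimated correlation, and 0.727 without MDA-MB-231_MCF7. Luminal differentiation genes (1.06, higher, 0 and 0 adjusted over the list alone, 0.0170) had adjusted p = 0.571 with an estimated correlation, 0.381 without MDA-MB-231_MCF7, 0.187 without SUM159PT and 0.0808 without MDA-MB-231. Extracellular matrix genes (−0.86, lower, 0 and 0 adjusted over the list alone, 0.00496) had adjusted p = 0.861 with an estimated correlation, and 0.201 without MDA-MB-231_MCF7. Without Hs578T the extracellular matrix list turned to higher, at 0.969. Ribosomal proteins (0.30, higher, 0 and 0 adjusted over the list alone, 0.0170) had adjusted p = 0.861 with an estimated correlation, 0.155 without SUM159PT_MCF7, 0.322 without MDA-MB-231 and 0.172 without Hs578T. Other lists passed only with a library left out. These were interferon genes (lower, adjusted p = 0.167, then 0.0145 without MDA-MB-231_MCF7 and 0.0130 without Hs578T), MHC class I genes (lower, 0.167, then 0.0302 without SUM159PT_BT-474 and 0.00482 without Hs578T) and luminal transcription factors (higher, 0.167, then 0.0225 without SUM159PT_MCF7 and 0.0312 without Hs578T). NF-kB and cytokine genes had 0.705, and 0.000161 without Hs578T. Without MDA-MB-231 EMT transcription factors had 0.00122 (0.267 with it), cholesterol synthesis 0.00503 (0.422) and fibroblast markers 0.000497 (0.267), and without SUM159PT_BT-474 the unfolded protein response had 0.0302 (0.527), all of them lower. For basal and myoepithelial, oestrogen receptor target, proliferation, NF-kB, immediate early and housekeeping genes, none of them past the threshold, the median, mean and test differed in sign.

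Each fusion was next set against its own 2 parents, which asks which parent it resembles. In the SUM159PT fusions, genes higher in SUM159PT lay near the mean of the parents, with median log2 ratios of 0.18 (905 genes, SUM159PT_T-47D), 0.28 (987 genes, SUM159PT_BT-474) and −0.14 (879 genes, SUM159PT_MCF7). Genes higher in the luminal parent lay below it, at −1.91 (732 genes), −1.82 (867 genes) and −1.70 (614 genes). In MDA-MB-231_MCF7 both sets lay below the mean, at −0.69 (919 basal-high genes) and −0.42 (529 luminal-high genes). On log2(RPM + 1), the SUM159PT fusions were closer to the higher parent for 84.0%, 90.0% and 80.1% of basal-high genes. For luminal-high genes the shares there were 21.7%, 22.3% and 27.4%, and in MDA-MB-231_MCF7 they were 55.5% (basal-high) and 64.7% (luminal-high). On this scale the mean of the 2 parents is itself closer to the higher parent for every such gene. All these shares lie below that level, so a high share does not show that a parent dominates. The basal-high minus luminal-high difference was 2.09, 2.10 and 1.56 in the SUM159PT fusions and −0.27 in MDA-MB-231_MCF7, with a mean of 1.37 ± 1.12 (SD, n = 4, exact sign-flip permutation p = 0.25, two-sided, where 0.125 is the smallest possible). The mean was 0.55 for genes that differed at least 2-fold between the parents and 2.11 at 8-fold or more, each with exact permutation p = 0.25. With 1 library per fusion no test within a fusion was made, and the difference between MDA-MB-231_MCF7 and the others was not tested.

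Only genes that qualified in at least 3 fusions were ranked. Among those higher in the luminal parent, TFF1 lay lowest, at a mean log2 ratio to the parental mean of −9.52 ± 1.87 (SD over 3 fusions). AF401035 (−8.07 ± 0.99), BC071816 (−7.16 ± 0.66) and IGFBP5 (−7.14 ± 2.86 over 4 fusions) followed. Each of these was listed at 0 in some of its fusions, where the ratio depends on the pseudocount of 1. Highest of the 309 genes were CTXN1 (0.50 ± 0.58), BATF (0.59 ± 0.70), BC082993 (1.07 ± 0.47) and RP1-125M3.2-001 (1.41 ± 0.64 over 4 fusions). Among genes higher in the basal-like parent, IL1RL1 (−4.93 ± 0.38), SERPINB3 (−4.22 ± 1.60), XAGE2 (−4.22 ± 1.26) and MYBPC1 lay lowest of 601 genes. MYBPC1 was listed at 0 in all 3 SUM159PT fusions, against 38.11 RPM in SUM159PT. MCAM (2.04 ± 1.11), ROS1 (2.08 ± 0.14), TBX18 (2.17 ± 0.78) and COL1A1 (2.51 ± 1.64) lay highest. TBX18 was at 22.55 RPM in SUM159PT, 0 in each luminal line, and 29.75, 88.11 and 60.6 RPM in its 3 fusions. COL1A1 was at 196.72 RPM in SUM159PT and at 187.83, 1077 and 1326 RPM in the fusions. Of the luminal-high epithelial junction and splicing genes, 14 of 17 in MDA-MB-231_MCF7 were within 2-fold of MCF7 or above it, against 0 of 22 in SUM159PT_T-47D, 0 of 19 in SUM159PT_BT-474 and 1 of 21 in SUM159PT_MCF7. Luminal-high oestrogen receptor targets were low in MDA-MB-231_MCF7 too, with a median log2 ratio of −2.23 over 8 genes, and TFF1 was at 11.83 RPM there against 4640 RPM in MCF7.

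**Figure D4:**
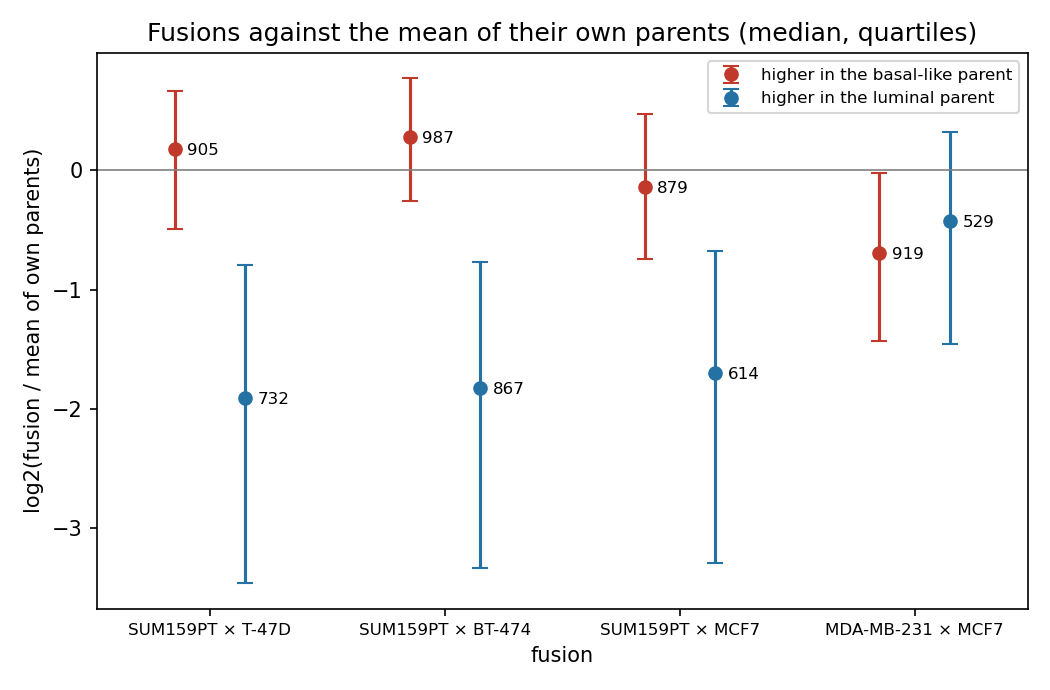
Median log2 ratio of the fusion to the mean of its 2 parents (y axis) for basal-high and luminal-high genes in each of the 4 fusions, with bars for the quartiles over genes and the gene numbers beside the points. Luminal-high medians are −1.91, −1.82 and −1.70 in the SUM159PT fusions and −0.42 in MDA-MB-231_MCF7.

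The spread within each class was measured because the series concerns heterogeneity among basal-like cells. The genes with the largest SD among basal-like lines were IRX2 (2609 RPM in SUM159PT, 0 in the other lines of the class), SAA1 (1859 and 1716 RPM in SUM159PT and MDA-MB-231, 0 in Hs578T) and COL1A2 (0, 12.56 and 3158 RPM in SUM159PT, MDA-MB-231 and Hs578T). THY1 (892 RPM in Hs578T, 0 in the others) and SPARC (348, 1.14 and 3958 RPM) followed. Among luminal lines they were TCN1 (3001 RPM in BT-474, 0 in the others), TFF1 (4640, 0.95 and 1883 RPM in MCF7, T-47D and BT-474) and KRT81 (2636 RPM in MCF7, at most 1.43 in the others). SERPINA6 (1123 RPM in T-47D, 0 in the others) and GNG11 (664 RPM in T-47D, 0 in the others) followed. Across 12738 genes, 1 − r averaged 0.237 ± 0.00594 (SD of 3 pairs) between basal-like lines and 0.199 ± 0.0119 between luminal lines, a difference of 0.0380 (exact permutation p = 0.3, two-sided, smallest possible 0.1). The pairs, which share lines, ranged from 0.231 to 0.243 and from 0.190 to 0.213. The median absolute log2 difference was 0.670 ± 0.0191 and 0.686 ± 0.0368, a difference of −0.0159 (exact permutation p = 0.9), and it was 0.0135 without BT-474. The SD was larger among basal-like lines for 49.6% of genes. These correlations are across genes, which are not independent replicates, and 3 lines against 3 cannot reach a p under 0.05. Since the permuted assignments mix the classes, these p do not decide whether basal-like lines are less alike than luminal lines.

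The comparisons of basal-like lines and of fusions with luminal lines share the 3 luminal libraries, which alone makes their fold changes correlate. Genes such as GSTP1, MSN, AKR1B1 and IL8 were higher and ESR1, GREB1, XBP1 and TFF3 lower in both. The fold changes of 12738 genes correlated across genes at r of 0.875, against 0.534 ± 0.0104 (SD of 100 simulations) for unchanged groups set against the same luminal libraries, and their covariance was 1.54 against 0.280 ± 0.00894. Of the genes called higher, 240 were shared by both comparisons, against 12.2 for independent lists, and of those called lower 91 were shared, against 2.93. Simulated unchanged groups shared 0 on average, which follows from the few calls such groups allow and says nothing about the overlap. The simulated correlation and covariance already include the sharing of luminal libraries, while the numbers for independent lists do not. The 3 luminal libraries are too few to be divided between the comparisons, so part of the excess of shared calls over independent lists may come from the shared controls.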

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

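The tests of mixture, mislabelling and the basal-like parent for MDA-MB-231_MCF7, and of unfused cells for the SUM159PT fusions, were chosen after the results were seen, and the splits of the samples and the tests of chromosome loss and depth were not. Of 80 groups of 4 fusions, 13 held 1 library far from the other 3. Chance gives about 1 in 20 groups, or 4, only if the fusions are exchangeable and the groups independent. Neither holds, since 3 of the fusions share SUM159PT and some of the genes are members of the lists. No excess over chance follows from the 13. MDA-MB-231_MCF7 was the library apart in 11 of the 13. It stood apart in CDH1 (381.79 RPM against 0 to 0.77), CLDN3 (57.46 against 0 to 0.44), ESR1 (2.19 against 0), IGFBP5 (20.16 against 0 to 0.36), KRT18 (1918.91 against 137.13 to 177.92), SRGN (120.07 against 487.43 to 532.57), VIM (17.53 against 1809.34 to 3938.05) and ZEB1 (0 against 14.16 to 20.62). It also stood apart in mean log2(RPM + 1) of the epithelial junction and splicing list (6.48 against 1.3 to 1.76), the basal and myoepithelial list (4.50 against 2.53 to 2.66) and the EMT transcription factors (1.53 against 4.30 to 4.53). For ESR1 the other 3 fusions were listed at 0, so any value above 0 would have stood apart. A 0 is compatible with up to 1.75 RPM in SUM159PT_T-47D, close to the 2.19 RPM. SUM159PT_MCF7 stood apart in LDHA (1368.62 RPM against 1827.13 to 1907.49) and in the MHC class I list (4.98 against 6.70 to 7.03).

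MDA-MB-231_MCF7 kept epithelial genes that the other fusions lacked. A mix-up with another line of this series is argued against. The correlations of MDA-MB-231_MCF7 across genes with MCF7 (0.836) and MDA-MB-231 (0.819) exceeded that with any other parental line by at least 0.0828. Only the lines of this series were compared, so a line from outside it or a contaminated culture was not tested. Unfused MCF7 cells or a mixture of unfused parents as the whole cause is argued against too: junction genes near the MCF7 level need a share of 50% or more, but 38.9% (95% binomial interval 23.1% to 56.5%) of 36 other genes that were at 100 RPM or more in MCF7 and below 1 RPM in MDA-MB-231 lay below 12.5% of the MCF7 level, with a median of 17.1% (bootstrap 95% interval 8.05% to 32.1%), although no line was profiled in 2 cultures. The matching 47 genes of MDA-MB-231 that MCF7 lacked had a median of 21.0% of the MDA-MB-231 level (bootstrap 95% interval 13.9% to 30.1%). Why the genes of both parents lay low was not tested. The basal-like parent could not be told apart from a chance property of this fusion, since MDA-MB-231 was a parent of 1 fusion. A biological difference between fusions of MDA-MB-231 and of SUM159PT therefore stays a hypothesis, and the difference was not tested.

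Luminal-high genes lay below the mean of the parents in the 3 SUM159PT fusions. Unfused SUM159PT cells as the whole cause are argued against: genes at 100 RPM or more in the luminal parent and below 1 RPM in SUM159PT had medians of 0.713%, 0.548% and 0.265% of the luminal level in SUM159PT_T-47D, SUM159PT_BT-474 and SUM159PT_MCF7, so that fused cells at the mean of the parents would need at least 92.9%, 96.7% and 95.6% unfused cells, but the matching SUM159PT genes had medians of 50.6%, 56.8% and 34.0% (bootstrap 95% upper limits 58.7%, 68.1% and 40.6%), although no line was profiled in 2 cultures. Loss of luminal chromosomes stays open. The state of a gene was a log2 ratio above or below the median of its fusion, which is not presence or loss. Neighbouring luminal-high genes shared their state more often than shuffled genes in these fusions. The excess was 5.13 points (permutation p = 0.0091, one-sided), 7.09 points (permutation p = 0.0003, one-sided) and 9.69 points (SD 2.31, permutation p = 0.0001, one-sided, the smallest possible). In MDA-MB-231_MCF7 it was 2.19 points (SD 2.45, permutation p = 0.2013, one-sided). The 9.69 points lie under the 10 points set as the bound against chromosome loss by less than their spread. A chromosome was known for 80.6%, 77.7% and 81.1% of the luminal-high genes in the 3 SUM159PT fusions, and the rest were left out. A part played by unfused cells stays open, and silencing of luminal genes was not tested apart from loss.

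The BT-474 library listed 5503 genes at 0, against 10781 to 12685 in the others. Depth alone is argued against, because BT-474 thinned to the depth of SUM159PT_BT-474 listed 6967 genes at 0 (SD 24.5) against 10781 there. The authors' processing stays open, since 37.2% of the low values of BT-474 were whole reads and 1087 genes lay below 1 read, against at most 495 genes in the other libraries. No biological explanation was tested.

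Other splits of the same libraries were counted for each comparison. For basal-like against luminal lines the 10 splits are too few for a share under 0.05: 1 of them, the real one, gave 980 genes (highest other 1), and 1 gave 13 lists (highest other 12). For fusions against luminal lines chance was not excluded for genes, since 2 of 35 splits gave 357 or more. The highest other, 539, set MDA-MB-231_MCF7 and the 3 luminal lines against the 3 SUM159PT fusions, which points to a structure of the samples. For lists 1 of 35 splits gave 14 (highest other 13), which excludes chance only if the 7 libraries are exchangeable, while 3 of the 4 fusions share SUM159PT. The margin was 1 list, and the count was 11 with the SUM159PT fusions alone and 4 with an estimated correlation. For fusions against basal-like lines the real split gave 0 genes in limma (669 at an unadjusted p under 0.05, highest other 144), so that all 35 of 35 splits had to give as many and their number says nothing. Chance was not excluded for lists, since 26 of 35 splits gave 6 or more (highest other 11).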

How the results depend on the processing

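The fits of genes and lists in the 3 SUM159PT fusions and their luminal parents with no block, and the fits of the lists with libraries left out, with the SUM159PT fusions alone and with the block, were chosen after seeing the data. Count tests on whole reads were not run. Over the alternatives, 0 of 65 genes named past the threshold in basal-like against luminal lines and 0 of 46 in fusions against luminal lines changed direction. Of these genes 39 and 26 kept their call in every alternative that tested them. The filter of 20 RPM tested only 60 of the 65 and 41 of the 46. Among the 39 were VIM, GSTP1, FOXA1, GATA3 and ESR1, and among the 26 AKR1B1, GSTP1, GREB1, ESR1 and XBP1. Estimated depths of 1.05 to 4.35 M reads limit genes near 5 RPM, where counting error alone is 21.4% to 43.7%.

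Basal-like against luminal lines gave 980 genes, and 615 with only the 2 groups compared, where fewer libraries set the variance, and 629 to 1202 with 1 library left out. Fusions against luminal lines gave 357, and 835 with the SUM159PT fusions alone, 1288 with the luminal parent as a block, 1201 for the same samples without the block, and 155 to 835 with 1 library left out. Fusions against basal-like lines gave 0 in limma (669 at an unadjusted p under 0.05), and 0 to 4 with 1 library left out. With an estimated correlation the lists past the threshold were 4, 4 and 0, in place of 13, 14 and 6. Among lists in the same 6 libraries, the block changed the call of the ERBB2 amplicon (0.117 without, 0.0151 with it) and of no other. Basal and myoepithelial and hypoxia genes were lost and study regulators gained there with and without it.

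Of the lists past the threshold, extracellular matrix in fusions against basal-like lines (lower, camera adjusted p = 0.00496) turned to higher without Hs578T (0.969). The mean log2(RPM + 1) of its 23 members was 8.70 in Hs578T, 4.73 in SUM159PT, 3.80 in MDA-MB-231 and 2.85 to 5.14 in the fusions. The call therefore rested in part on Hs578T, a parent of no fusion. Why that line stood high was not tested. The other signs that changed were of values short of the threshold. UTX in basal-like against luminal lines ranged from −0.97 to 0.12 with 1 library left out. In fusions against basal-like lines the ranges were −0.0277 to 2.83 for CDH1, −1.34 to 0.55 for EN1, −0.55 to 0.0147 for ESR1, −0.42 to 0.85 for KRT18, −2.07 to 0.38 for TCF4 and −0.48 to 0.62 for UTX. The SUM159PT fusions alone gave −0.0277 for CDH1, 0.55 for EN1, −0.42 for KRT18 and 0.26 for TCF4, and without Hs578T EN1 was 0.54, ESR1 0.0025, TCF4 0.38 and UTX −0.48. The camera p of lists short of the threshold that changed direction was 0.409 (interferon) and 0.875 (ribosomal) for the SUM159PT fusions against luminal lines, 0.453 and 0.867 with the block, 0.441 and 0.843 for the same libraries without it, and 0.582 (EMT transcription factors) and 0.941 (chromatin regulators) against basal-like lines. The spread difference in median absolute log2 difference ranged from −0.0572 to 0.0135. Where fewer samples do not account for a change, the cause was not tested.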

Other observations

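These genes were chosen after their values were seen. Some genes were high in a fusion and near 0 in both of its parents. With both parents under 3 RPM and the fusion at 30 RPM or more, there were 14 such gene entries in MDA-MB-231_MCF7, 4 in SUM159PT_T-47D, 5 in SUM159PT_BT-474 and 4 in SUM159PT_MCF7. In MDA-MB-231_MCF7 they included OLFML3 (141.22 RPM), RARRES1 (115.69), the basal keratins KRT5 (110.83) and KRT6B (35.72), UBD (58.05) and VGLL1 (37.69). The entry HNOEL-ISO (149.76 RPM) had the same parental values as OLFML3 (0 and 1.54 RPM), so the 14 may count a gene more than once. SULT1E1, an oestrogen sulfotransferase gene, was at 140.28 RPM in SUM159PT_MCF7 and 34.1 RPM in SUM159PT_T-47D, against 2.46 RPM in SUM159PT and 0.62 and 0 RPM in MCF7 and T-47D. CXCL5 was at 37.17 RPM in SUM159PT_T-47D, and G0S2 at 34.74 and AZGP1 at 33.64 RPM in SUM159PT_BT-474. Each value comes from 1 library and has no replicate check.

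Few luminal genes stayed high in a SUM159PT fusion. Of genes at 50 RPM or more in the luminal parent and below 1 RPM in SUM159PT, 2 of 90 in SUM159PT_T-47D, 2 of 100 in SUM159PT_BT-474 and 0 of 72 in SUM159PT_MCF7 kept 50% or more of the luminal level. CDKN2A was at 0 RPM in SUM159PT, 81.93 in T-47D and 137.55 in SUM159PT_T-47D. HOXB7 was at 0.78 RPM in SUM159PT, 129.21 in BT-474 and 80.19 in SUM159PT_BT-474.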
